A study of Mus musculus with 30 samples.

How the data were processed

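The series profiles lymphoid cells of C57BL/6 mice in which Crebbp was deleted with an inducible Cre. Its 30 samples comprise ChIP-seq for H3K27ac, H3K18ac, H3K56ac and CBP, an input and 14 RNA-seq libraries. Peak lists for 15 samples were analysed: 1 H3K27ac list each of wild-type and Crebbp-null progenitors, 2 lists per mark for wild-type B cells and Crebbp-null LPD, and 1 CBP list of wild-type B cells. The RNA-seq libraries and the input, 15 samples, were not analysed here. Groups follow the sample labels.

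Per the submitters' processing notes, the authors used Bowtie2 2.1.0, Picard, MACS2 2.0.10 and bedtools, with coordinates on mm10. The notes as used here give no settings. Each deposited file is a list of peak positions (chromosome, start, end) called per library, with no score, height or p-value, so the unit of the authors' values is a position. No read depth can be taken from these files, and the peak number and covered length per list stand in its place. The peaks of a list did not overlap each other, and the narrowest was 200 bp in each list.

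Everything from the lists onward was computed here with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with Matplotlib 3.10.9. Regions are the merged union of the 4 lists of a mark, and a list has a region when at least 1 bp of a peak overlaps it. A region is gained when both LPD lists and neither B cell list have it, lost in the reverse case and kept when all 4 have it. The same counts were made for the other 2 pairings of the 4 lists. Peak number and covered length were compared on the log2 scale with an exact two-sided permutation test, which cannot go below p = 0.333. Progenitors, with 1 library per genotype, were described without a test.

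The plan assigned regions to transcription start sites. The gene table (RefSeq genes of assembly GRCm38.p6, the same as mm10) gives gene spans but no strand, so the plan could not be followed. Each region was instead assigned to every protein-coding gene whose span, widened by 1 kb, it overlaps, and otherwise to the gene with the nearest end within 50 kb. Assigning to every overlapping gene lets long genes collect many regions, and a region inside a gene need not act on it. Regions within 1 kb of either gene end took the place of promoter regions. There were 21631 protein-coding genes, and all 315 entries of the fixed gene groups matched one, 2 of them by an older symbol.

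The 17 gene groups were B cell identity, early B cell development, MHC class II presentation, germinal centre, plasma cell, myeloid, T and NK, erythroid and megakaryocyte, stem and progenitor, proliferation, DNA damage and p53, acetyltransferases and deacetylases, lymphoma oncogenes and suppressors, NF-kB, cAMP and immediate early genes, and housekeeping and non-blood controls. For each group, mark and direction, the number of members with a called region was compared with 10000 random gene lists of the same size matched on region number in 8 bins, among genes with at least 1 region of that mark. One-sided permutation p-values were adjusted by Benjamini-Hochberg over all 204 tests.

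Loss with and without a CBP peak, overlaps between marks and the overlap between progenitor and LPD differences were given as odds ratios, with 0.5 added to each cell, and 95% intervals from 10000 bootstraps over chromosomes. Pooled values within width quartiles are Mantel-Haenszel odds ratios. For CBP, width was the mean length that the B cell lists cover in a region. Intervals cover variation over chromosomes, not between animals, since regions are not independent replicates.

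Genes named for the comparisons follow a fixed rule: Crebbp and Ep300; the 10 genes per direction (5 for H3K18ac and H3K56ac) with the most called sequence; up to 4 members per gene group with called regions; the 10 with the most sequence called in all 3 marks; and the 10 with the widest CBP peak, as no score is given. Lengths in kb per gene are sums of peak length over all regions assigned to it, except for Crebbp and Ep300, where only the span and 1 kb around it were used. Some genes that meet the rule are not reported here. Genes outside the rule, which are those of the sex chromosomes, those in the further observations and 4 early B cell genes in progenitors, were named after their values were seen.

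Region calls, gene group tests and the odds ratio of loss in LPD were tested on simulated data made from the real lists. The progenitor comparison, overlaps between marks and values within width quartiles were not. Planted gains and losses were recovered at 71.6 and 72.1% over 40435 H3K27ac regions, 59.8 and 59.7% over 44756 H3K18ac regions, and 57.3 and 57.9% over 34515 H3K56ac regions, while 3.28, 4.02 and 4.37% of unchanged regions were called. Detection rates were taken from the B cell lists and applied to the LPD lists as well. These shares therefore do not cover groups whose lists differ in sensitivity. Of 200 random gene lists per mark, 3.5, 2.5 and 3.5% fell under an unadjusted p of 0.05, and 100% of planted lists did. Calls were planted at most members of each planted list, and p was not adjusted. The 100% therefore does not give the power for weaker effects, smaller groups or adjusted p-values. A planted odds ratio of 0.3 lay inside the interval in 48, 47 and 48 of 50 simulations. The CBP flag was drawn there at random over the real regions, and loss was drawn for each region on its own, without peak lists. This checks the calculation only, not cases where CBP and loss depend on width or where losses cluster.

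Alternatives covered the overlap that counts, the upper part of each list by width, lists of equal length, 1 kb tiles, joining of peaks within 1 kb, each library left out, gene assignment (gene ends only, or within 10 kb), Fisher's exact test, region width, gene-end regions apart, and pairing by replicate number. Where a peak score was meant to rank peaks, width was used.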

Results

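The data describe histone acetylation in mouse lymphoid cells with and without Crebbp, the gene of the histone acetyltransferase CBP. Chromatin immunoprecipitation with sequencing gave 15 lists of peaks: 14 for histone acetylation and 1 for CBP itself. Wild-type B cells were sorted from spleen by B220, and had 2 lists for each of H3K27ac, H3K18ac and H3K56ac, with the single CBP list. Crebbp-null lymphoproliferative disease (LPD) was profiled as unsorted spleen, with 2 lists per mark. Lymphoid progenitors, sorted from bone marrow as lineage-negative cells with the IL-7 receptor, had 1 H3K27ac list per genotype. LPD and B cells therefore differed in genotype, disease and sorting at once, and the labels do not say whether replicates came from separate animals. Values are given as mean ± SD over 2 libraries where there were 2.

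The lists held 17124 peaks in wild-type progenitors and 13125 in Crebbp-null progenitors. For H3K27ac they held 30360.5 ± 230 peaks in B cells and 29752.5 ± 3071 in LPD (SD, n = 2 each), a log2 ratio of -0.03. For H3K18ac they held 22970.5 ± 687 and 37388 ± 3028 peaks, a log2 ratio of 0.70, and for H3K56ac 19577.5 ± 1152 and 28578 ± 503, a log2 ratio of 0.55. Peaks covered 26.8 ± 0.506 Mb of the genome in B cells and 22.2 ± 5.60 Mb in LPD for H3K27ac. The same lengths were 13.7 ± 0.482 and 25.4 ± 5.68 Mb for H3K18ac, and 10.01 ± 0.803 and 17.7 ± 0.883 Mb for H3K56ac. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333. Its p was 1 for the H3K27ac peak number and 0.333 for those of the other two marks. The CBP list had 1000 peaks over 0.305 Mb. Read depth is unknown, since the lists give positions only.

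**Figure D1:**
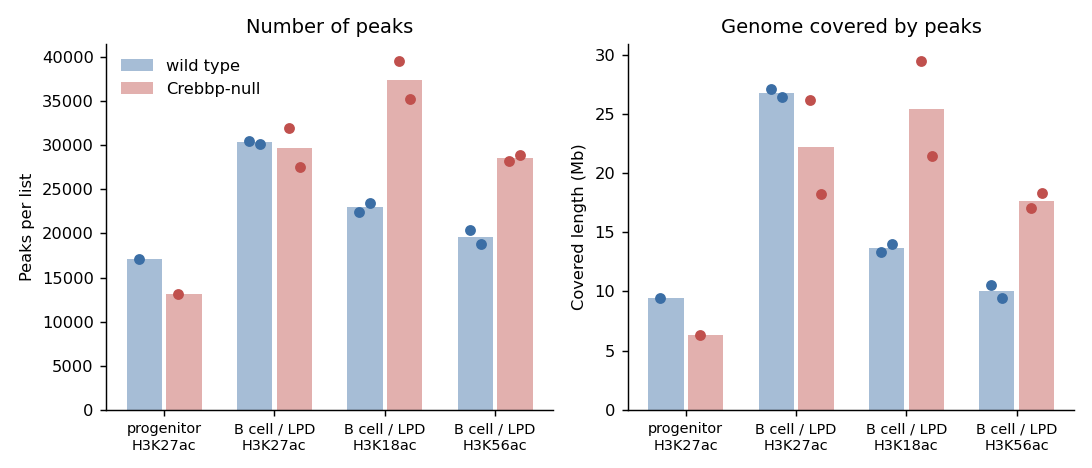
Number of peaks (left) and genome length covered in Mb (right) for each list; points are libraries and bars are group means. H3K18ac and H3K56ac covered more of the genome in LPD than in B cells (25.4 against 13.7 Mb and 17.7 against 10.01 Mb), whereas H3K27ac covered 22.2 against 26.8 Mb.

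Crebbp itself (chromosome 16, 4081334 to 4213957) had acetylation peaks in each of the 14 acetylation lists. Over its span and 1 kb on either side, H3K27ac peaks covered 1.79 ± 0.0410 kb in B cells and 1.62 ± 0.0912 kb in LPD (SD, n = 2 each). H3K18ac covered 1.10 ± 0.206 and 1.31 ± 0.366 kb, and H3K56ac 0.662 ± 0.0891 and 1.67 ± 0.0325 kb. In progenitors, H3K27ac covered 0.507 kb at Crebbp in wild type and 0.239 kb in the null. Peaks over the gene do not check its deletion, because the position of the deleted part is not in the labels. At Ep300, the gene of the related acetyltransferase p300 (chromosome 15, 81586209 to 81652077), H3K27ac covered 1.71 ± 0.158 kb in B cells and 2.15 ± 0.0396 kb in LPD. For H3K18ac the Ep300 values were 1.13 ± 0.0778 and 1.67 ± 0.224 kb, and for H3K56ac 1.21 ± 0.00636 and 2.29 ± 0.279 kb. Progenitors had 1.35 kb in wild type and 1.27 kb in the null at Ep300. The CBP list had a peak at neither gene.

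How acetylation in Crebbp-null LPD differs from that of wild-type B cells was asked for each mark. A region was called gained when both LPD lists and neither B cell list had a peak in it, lost in the reverse case, and kept when all 4 lists had one. For H3K27ac, the gene with the most gained sequence was Rftn1, which encodes raftlin, a lipid raft protein of B cells (chromosome 17, 49993258 to 50190497). It gained 12 regions with 20.5 kb, and its assigned H3K27ac went from 38.8 ± 1.44 kb in B cells to 61.3 ± 10.9 kb in LPD (SD, n = 2 each). Its widest gained region lay at 50067697 to 50074590. The transcriptional repressor gene Zbtb20 (chromosome 16, 42875689 to 43634392) gained 17 regions, with 2.64 ± 0.183 kb in B cells and 37.3 ± 14.1 kb in LPD. Wipf3 had no H3K27ac in either B cell list and 12.5 ± 1.36 kb in LPD, and the semaphorin co-receptor gene Nrp2 had 2.31 ± 0.607 and 19.8 ± 3.95 kb. The E-protein gene Tcf4 had 13.0 ± 0.526 and 30.5 ± 13.4 kb. The sialyltransferase gene St3gal1 had 16.6 ± 0.166 and 37.9 ± 2.28 kb. Foxn3, Cmah and Atxn1 completed the 10 genes with the most gained sequence, with 15.1, 14.3 and 13.2 kb. Foxp1, a transcription factor gene needed in B cell development, was among the top 10 in both directions, with 16 gained regions (18.1 kb) and 22 lost regions (18.5 kb).

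Losses of H3K27ac were led by Sorl1, a sorting receptor gene (chromosome 9, 41964709 to 42124297). It lost 19 regions with 23.4 kb and had 39.6 ± 0.0672 kb in B cells and 3.35 ± 1.88 kb in LPD (SD, n = 2 each). Armc9 had 21.2 ± 0.0368 and 1.21 ± 0.364 kb, and Lpp 29.3 ± 0.909 and 1.35 ± 0.643 kb. The kinase gene Lrrk2 (chromosome 15, 91672791 to 91816124) had 17.4 ± 0.315 kb in B cells and none in either LPD list. The sialyltransferase gene St6gal1, whose product makes the ligand of CD22, had 25.6 ± 0.0792 and 2.04 ± 1.59 kb. Cyth1 lost 22 regions, from 58.7 ± 1.49 to 16.1 ± 4.42 kb, and the B cell repressor gene Bach2 lost 16, from 53.9 ± 1.68 to 28.3 ± 9.99 kb. Ttll5 and Arhgap26 each had less than 3 kb in LPD, at 2.33 ± 1.12 and 0.961 ± 0.489 kb, against 25.8 ± 0.174 and 16.1 ± 0.153 kb.

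**Figure D2:**
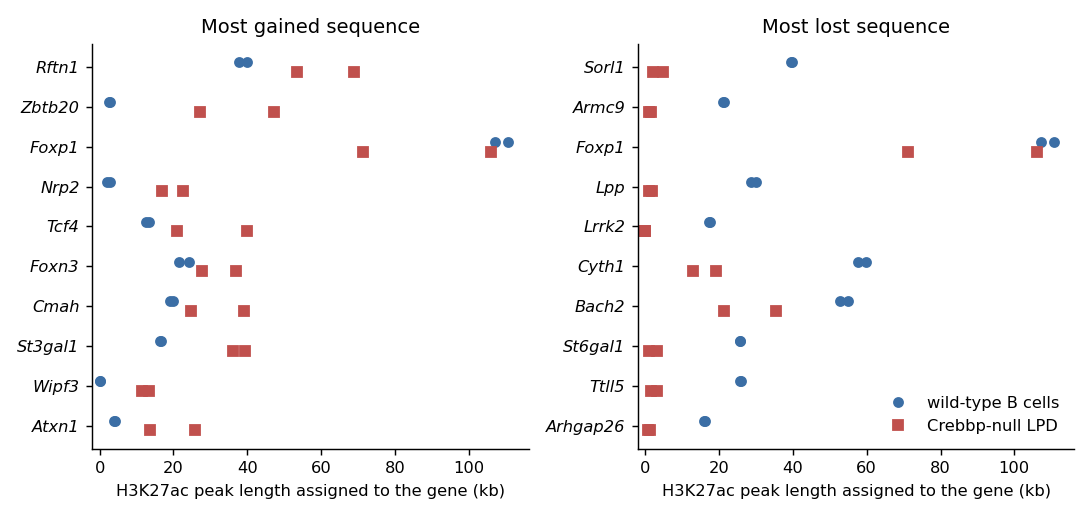
H3K27ac peak length in kb assigned to the 10 genes with the most gained (left) and the most lost (right) sequence. Points are libraries of B cells and LPD. Sorl1 had a mean of 39.6 kb in B cells and 3.35 kb in LPD, and Wipf3 had none in B cells and a mean of 12.5 kb in LPD.

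Over the genome, 4628 of 40435 H3K27ac regions were gained and 6445 lost, so that 27.3% of the regions of both B cell lists were lost in LPD. Of gained regions 14.7% lay within 1 kb of a gene end, as did 12.6% of lost regions, against 58.3% of the 14745 kept regions. The other 2 ways to pair the 4 lists gave 298 and 414 such regions in all, against 11073 for the real grouping. Regions of the same group overlapped more (Jaccard index of covered bases 66.0 to 80.7%) than regions of different groups (43.1 to 48.1%). The balance of gains and losses rested on the second LPD list, the shortest of the 4: without it 10315 regions were gained and 6574 lost, a log2 ratio of 0.65 in place of -0.48. Without the second B cell list the lost regions numbered 10023.

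Rftn1 also had the most gained H3K18ac, with 38 regions and 44.7 kb, from 16.6 ± 1.30 kb in B cells to 79.4 ± 5.29 kb in LPD (SD, n = 2 each). Foxp1 gained 30 regions and went from 38.7 ± 1.56 to 90.3 ± 24.0 kb. The span of the thyroglobulin gene Tg (chromosome 15, 66670754 to 66850721) gained 23 regions, from 5.65 ± 0.194 to 40.3 ± 2.45 kb. Ankrd55 and the Hippo kinase gene Stk3 gained 21.4 and 20.7 kb. H3K18ac losses were led by Wwox (10.8 ± 0.752 and 2.26 ± 0.923 kb), Lrrk2 (7.10 ± 0.0672 kb and none), Lpp (18.6 ± 0.337 and 3.87 ± 1.23 kb), the integrin gene Itga9 (6.48 ± 0.146 kb and none) and the cAMP phosphodiesterase gene Pde4d (5.20 ± 0.252 and 0.271 ± 0.383 kb). For H3K56ac, Rftn1 led again, with 33 gained regions and 8.21 ± 1.49 and 49.7 ± 1.04 kb. It was followed by Zbtb20 (1.52 ± 0.0332 and 25.6 ± 1.15 kb), Foxp1 (24.3 ± 1.76 and 60.5 ± 5.39 kb), the adaptor gene Grb2 (3.19 ± 0.429 and 28.7 ± 2.54 kb) and the ezrin gene Ezr (6.30 ± 0.153 and 31.9 ± 0.885 kb). Lpp, Lrrk2, Wwox, Ttll5 and Prag1 lost the most H3K56ac, between 3.76 and 5.15 kb each.

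Gains outnumbered losses for both of these marks: 11200 against 1735 of 44756 H3K18ac regions, and 8183 against 1453 of 34515 H3K56ac regions. With 1 list left out the rule needs 1 list fewer. Lost H3K18ac regions then numbered 3574 without B cell list 1, 3146 without B cell list 2 and 2897 without LPD list 1, and gained ones 20914 without LPD list 2. Lost H3K56ac regions numbered 2579 and 3257 without B cell list 1 or 2, and gained ones 12703 without LPD list 1. Over the 4 pairings of 1 LPD list with 1 B cell list, the log2 ratio of gained to lost regions was 2.22 ± 0.55 for H3K18ac and 1.98 ± 0.27 for H3K56ac. When every list was shortened to the length of the shortest by keeping its widest peaks, 5214 H3K18ac regions were gained and 3703 lost, and 3821 H3K56ac regions were gained and 2475 lost. The other pairings of lists gave 441 and 526 regions for H3K18ac against 12935, and 318 and 392 for H3K56ac against 9636.

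**Figure D3:**
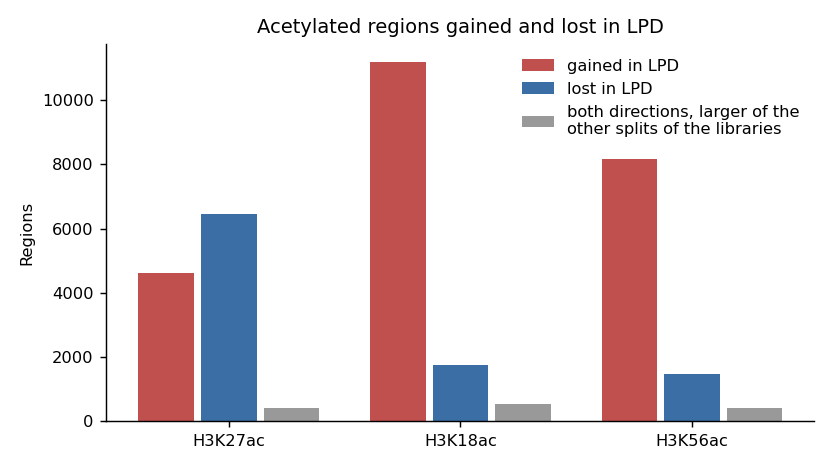
Number of regions gained (peaks in both LPD lists and no B cell list) and lost (the reverse) for each mark. H3K27ac had 4628 gained and 6445 lost regions, whereas H3K18ac had 11200 and 1735, and H3K56ac had 8183 and 1453.

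Genes of cell division gained regions more often than matched lists in all 3 marks before adjustment. Of 21 such genes with H3K27ac regions, 8 gained a region and 0 lost one, where random gene lists matched on region number gave 3.04 gains (one-sided permutation p = 0.0042, adjusted p = 0.214). The proliferation marker gene Mki67 had 0.189 ± 0.267 kb of H3K27ac in B cells and 3.96 ± 1.16 kb in LPD (SD, n = 2 each). The cyclin gene Ccnb2 had none in B cells and 1.11 ± 0.407 kb in LPD, and the mitotic kinase gene Aurkb had 1.83 ± 0.0955 and 2.67 ± 1.02 kb. For H3K56ac 11 of 20 gained a region and 1 lost one (5.90 gains in matched lists; permutation p = 0.0084, adjusted p = 0.3196). For H3K18ac 9 of 19 gained a region and 0 lost one (5.48 in matched lists; permutation p = 0.0498, adjusted p = 0.505). With lists of equal length, the H3K27ac gain of this group passed the threshold, with 10 genes and an adjusted permutation p of 0.0204. No count of this group passed in any other alternative, Fisher's exact test included. With a library left out, the adjusted permutation p of its gains was 0.114 to 0.383 for H3K27ac and 0.138 to 0.442 for H3K56ac.

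Genes of early B cell development had lost regions more often than matched lists in all 3 marks before adjustment, although their summed H3K18ac and H3K56ac was longer in LPD. For H3K27ac 8 of 10 lost a region and 4 gained one (5.04 losses in matched lists; one-sided permutation p = 0.0257, adjusted p = 0.406). For H3K18ac 6 of 11 lost one (1.78 in matched lists; permutation p = 0.0027, adjusted p = 0.214), and for H3K56ac 5 of 10 (1.76 in matched lists; permutation p = 0.0118, adjusted p = 0.3196). With lists of equal length the H3K18ac losses were 6 against 4.10 in matched lists, and among the widest peaks of each list 3 against 1.28, each with an adjusted permutation p of 1. Without B cell list 2 of H3K56ac, 9 members lost H3K56ac against 3.06, with an adjusted permutation p of 0.0204. Gains were at 5 of the 11 and 4 of the 10, against 6.86 and 5.62 in matched lists. Summed over the group, assigned H3K27ac was 115 ± 1.48 kb in B cells and 96.4 ± 29.1 kb in LPD (SD, n = 2 each), H3K18ac 39.96 ± 1.97 and 102.7 ± 22.5 kb, and H3K56ac 25.9 ± 2.32 and 62.1 ± 5.03 kb. The receptor kinase gene Flt3 had 8.50 ± 0.335 kb of H3K27ac in B cells and 3.37 ± 0.398 kb in LPD (SD, n = 2 each), and Foxo1 13.7 ± 1.36 and 9.13 ± 2.09 kb. Ikzf1, the gene of Ikaros, went the other way, with 9 gained regions and 29.9 ± 0.856 and 49.7 ± 14.99 kb.

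Germinal centre genes lost H3K27ac at 6 of 10 members and gained it at 1, against 3.25 losses in matched lists (one-sided permutation p = 0.0236, adjusted p = 0.406). Irf8, a transcription factor of this stage, had 24.0 ± 0.242 kb in B cells and 3.90 ± 2.73 kb in LPD (SD, n = 2 each). Rgs13 had 6.95 ± 0.173 and 0.402 ± 0.568 kb, and Bcl6, the central repressor of the germinal centre, had 3.99 ± 0.139 and 1.18 ± 0.447 kb. For H3K18ac 3 of 9 members lost a region and 4 gained one (1.27 and 5.08 in matched lists). For H3K56ac 4 of 10 lost one (1.37 in matched lists; permutation p = 0.0277, adjusted p = 0.406) and 3 gained one (5.16).

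Of 23 B cell identity genes with H3K27ac regions, 13 lost a region and 8 gained one (12.7 and 10.8 in matched lists). Ebf1 lost 15 regions (51.7 ± 1.12 and 24.3 ± 7.17 kb in B cells and LPD; SD, n = 2 each), Bank1 lost 14 (25.1 ± 1.61 and 11.3 ± 5.60 kb), and the complement receptor gene Cr2 lost 6 (7.59 ± 0.875 and 0.158 ± 0.223 kb). For H3K18ac 18 of 23 gained a region and 7 lost one (16.9 and 4.12 in matched lists), and for H3K56ac 16 of 22 gained one and 6 lost one (16.3 and 4.76). Cd22 had 0.248 ± 0.0686 kb of H3K18ac in B cells and 9.61 ± 2.004 kb in LPD, and Pou2f2 had none and 5.69 ± 1.94 kb. None of these counts stood apart from matched lists (smallest unadjusted permutation p 0.0998), and marks were not tested against each other.

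Genes of antigen presentation by MHC class II gained H3K27ac at 1 of 15 members, against 5.91 in matched lists (one-sided permutation p = 0.004, adjusted p = 0.214). They lost it at 9, against 6.89 in matched lists (one-sided permutation p = 0.175). Without the second LPD list, 7 members gained it against 8.72 in matched lists, with an adjusted permutation p of 1. The invariant chain gene Cd74 lost 5 regions, from 14.4 ± 0.0750 to 8.28 ± 2.55 kb (SD, n = 2 each). Ciita, the master regulator of the class II genes, lost 4 regions and gained 2, with 10.2 ± 0.00849 and 6.52 ± 2.14 kb. For H3K18ac 6 members gained a region and 1 lost one (9.30 and 2.20 in matched lists), and for H3K56ac 10 gained one and 1 lost one (8.65 and 2.05).

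Among cAMP-responsive and immediate early genes, 10 of 18 lost H3K27ac regions and 2 gained them (6.32 losses in matched lists; one-sided permutation p = 0.0321, adjusted p = 0.406). The nuclear receptor gene Nr4a1 had 18.7 ± 0.00636 kb in B cells and 6.59 ± 0.939 kb in LPD (SD, n = 2 each), and Fos had 18.4 ± 1.06 and 7.11 ± 1.75 kb. Sik1, the gene of a salt-inducible kinase, gained 5 H3K27ac, 13 H3K18ac and 17 H3K56ac regions, and its H3K18ac went from 7.22 ± 1.02 to 40.6 ± 0.820 kb. For H3K18ac 5 of the 18 gained a region, against 10.3 in matched lists (one-sided permutation p = 0.0025, adjusted p = 0.214), and 3 lost one. Without B cell list 2 of H3K18ac, 11 lost a region against 4.15 in matched lists and 5 gained one against 11.9, each with an adjusted permutation p of 0.0306. For H3K56ac 7 gained one and 4 lost one (10.5 and 2.57 in matched lists).

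In the group of lymphoma oncogenes and suppressors, 14 of 25 genes gained H3K27ac regions and 10 lost them (10.3 and 12.2 in matched lists). The kinase gene Jak1 lost 11 regions, from 18.1 ± 0.745 kb in B cells to 5.03 ± 1.79 kb in LPD (SD, n = 2 each). The cyclin gene Ccnd2 had 1.56 ± 0.290 kb in B cells and 6.93 ± 1.46 kb in LPD, and Myc led the gains of H3K56ac in this group, with 2.497 ± 0.502 and 10.6 ± 1.27 kb. For H3K18ac 16 gained a region and 5 lost one (17.3 and 4.30 in matched lists), and for H3K56ac 14 gained one and 3 lost one (14.9 and 4.11).

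Of 17 NF-kB pathway genes, 7 gained and 9 lost H3K27ac regions (7.22 and 8.396 in matched lists). Nfkb1 had 14.97 ± 0.163 kb in B cells and 3.74 ± 1.21 kb in LPD (SD, n = 2 each), and Traf3, a negative regulator of the pathway, gained 4 regions in each mark. For H3K18ac 10 gained and 3 lost a region (11.5 and 2.78 in matched lists), and for H3K56ac 13 gained and 1 lost one (11.4 and 3.18). Plasma cell genes gained H3K27ac at 5 of 10 members and lost it at 3 (3.62 and 4.21). Creld2 had 1.06 ± 0.0382 and 4.27 ± 0.560 kb, whereas the syndecan gene Sdc1 had 2.39 ± 0.0460 kb in B cells and none in LPD. For H3K18ac 8 of 10 plasma cell genes gained a region, for H3K56ac 7 of 10 did, and 0 lost one in either mark (5.99 and 6.18 gains and 1.42 and 1.65 losses in matched lists). DNA damage and p53 genes gained H3K27ac at 4 of 25 and lost it at 6 (5.27 and 6.18 in matched lists), with Parp1 at 18.6 ± 0.364 and 6.95 ± 0.754 kb. Acetyltransferase and deacetylase genes gained it at 5 of 22 (5.69 in matched lists) and lost it at 3 (6.62; permutation p = 0.0425, adjusted p = 0.456), with 5 lost regions at Hdac9 and 1 gained region at each of Ep300 and Kat8.

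Marker groups of other blood cells, which the unsorted spleen could hold, were counted in the same way. Erythroid and megakaryocyte genes gained H3K27ac at 3 of 9 and lost it at 0 (1.72 and 1.98 in matched lists), and gained H3K18ac at 4 of 6 (one-sided permutation p = 0.0311, adjusted p = 0.406). The red cell anion exchanger gene Slc4a1 had no H3K27ac in B cells and 3.64 ± 1.12 kb in LPD (SD, n = 2 each). Myeloid genes gained H3K27ac at 1 of 6 and lost it at 2 (1.35 and 1.61 in matched lists), and gained H3K18ac at 5 of 9 (2.92). T and NK cell genes gained H3K27ac at 1 of 10 and lost it at 4 (2.19 and 2.52 in matched lists), with Cd2 at 17.2 ± 0.786 and 5.86 ± 2.55 kb. They lost H3K18ac at 4 of 9 (1.23 in matched lists, one-sided permutation p = 0.0216, adjusted p = 0.406). T and NK genes also gained H3K18ac at 5 of 9 (5.28 in matched lists). Their summed H3K18ac was 22.5 ± 0.96 kb in B cells and 23.5 ± 5.84 kb in LPD. Stem and progenitor cell genes gained H3K27ac at 3 of 10 and lost it at 5. They lost H3K18ac at 4 of 10 (1.38 in matched lists, permutation p = 0.0338, adjusted p = 0.406) and gained it at 6 (5.50). Summed H3K18ac of this group was 23.0 ± 0.557 kb in B cells and 28.1 ± 6.08 kb in LPD. Housekeeping genes gained H3K27ac at 2 of 14 and lost it at 2 (2.96 and 3.55 in matched lists). They gained H3K18ac at 2 of 14, fewer than the 5.16 of matched lists before adjustment, as the cAMP and immediate early genes did (one-sided permutation p = 0.03, adjusted p = 0.406). Of the non-blood genes with any H3K27ac region, Gcg and Gfap, both gained one (0.297 in matched lists; one-sided permutation p = 0.0126, adjusted p = 0.3196). For H3K18ac 1 of 3 non-blood genes gained a region (0.968 in matched lists). For H3K56ac the non-blood genes with a region, 3 in all, each gained one (0.917 in matched lists, permutation p = 0.0096, adjusted p = 0.3196). The group had no H3K56ac in either B cell list, so these genes entered the test only through LPD peaks. They could not lose a region, and the p rests on genes that LPD peaks selected. None of the 204 tests over the 17 gene groups, 3 marks and 2 directions passed an adjusted permutation p of 0.05. Before adjustment 20 were under 0.05, of which 14 were for more and 6 for fewer genes than in matched lists, and Fisher's exact test without matching gave 8 calls after adjustment.

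Whether the marks changed at the same places was asked next. Rftn1 had 97.6 kb of gained regions summed over the 3 marks, followed by Foxp1 with 74.3 kb, Zbtb20 with 63.5 kb, Foxn3 with 48.5 kb and Tcf4 with 47.7 kb. Nrp2, Wipf3, Prkce, Grb2 and Cmah had between 43.4 and 46.9 kb. Losses in all 3 marks were led by Sorl1 with 31.1 kb, Lpp with 31.1 kb, Lrrk2 with 30.4 kb, Armc9 with 24.96 kb, Foxp1 with 22.0 kb and Bach2 with 21.3 kb, and Wwox, Ttll5, Arhgap26 and Zfp608 had 18.5 to 20.5 kb. In all, 1761 genes gained regions in every mark and 414 lost regions in every mark. Of the 4324 merged regions that gained H3K27ac, 3076 (71.1%) gained H3K18ac and 2455 (56.8%) gained H3K56ac, and 0 lost either. Independent lists would share 862 and 490. The odds ratios were 13.9 (95% bootstrap interval 12.4 to 15.5) and 17.3 (15.5 to 19.6), but 5.85 and 6.97 without the second LPD list of H3K27ac, and 7.02 and 7.73 when peaks had to cover 50% of a region. Of the 6282 that lost H3K27ac, 933 lost H3K18ac and 671 lost H3K56ac, with odds ratios of 15.7 (13.2 to 19.02) and 13.3 (11.0 to 16.9). The first was 7.79, 9.06 and 9.85 without B cell list 1, B cell list 2 or LPD list 1 of H3K18ac. The second was 8.69 and 8.16 without B cell list 1 of H3K27ac or list 2 of H3K56ac. With peaks covering 50% they were 8.13 and 5.95, and with lists of equal length 6.53 and 5.49. Over only regions with peaks of both marks in both B cell lists, which could be lost in both, a count added after the data were seen, the odds ratios of losses were 156 and 155. Of all 6282 regions that lost H3K27ac, 49.9% had no H3K18ac peak in any list and 72.2% no H3K56ac peak, so those could not lose these marks. The labels do not state whether the 3 marks were profiled in the same cells.

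The listed CBP peaks of wild-type B cells lay mostly on acetylated chromatin. Regions with a CBP peak were lost in LPD less often than those without. The widest CBP peak, of 3533 bp, had no gene assigned. The widest with a gene covered 2439 bp at Cd74 and Tcof1 (chromosome 18, 60810672 to 60813110). Other wide peaks lay at the chemokine receptor gene Ccr1 (1287 bp), the transcription factor gene Klf2 (1095 bp), Sun2 and Tex14 (933 bp each), the AP-1 gene Jund (872 bp), Iqcn (832 bp) and Trim7 (822 bp). The peaks at Ccr1, Klf2, Sun2, Tex14 and Jund overlapped acetylation in all 12 B cell and LPD lists, and the Trim7 peak only H3K27ac of B cells. The peak at Cd74 and Tcof1 overlapped H3K27ac in both B cell lists and LPD list 1, and no H3K18ac or H3K56ac. The Iqcn peak overlapped no acetylation in any of the 12 lists. CBP peaks were assigned to 13 of 23 B cell identity genes, among them Ebf1, Cd22 and Cr2, and to 9 of 15 class II genes. They were also assigned to 8 of 18 cAMP and immediate early genes, 7 of 17 NF-kB genes and 5 of 14 housekeeping genes, and to 0 of the proliferation, myeloid, erythroid and non-blood genes. These counts were not compared with matched lists. Of the 1000 peaks, 88.8 and 87.7% overlapped H3K27ac in the 2 B cell lists and 82.3 and 71.1% in the 2 LPD lists. For H3K18ac the shares were 75.3 and 76.9% in B cells and 82.3 and 72% in LPD, and for H3K56ac 64.6 and 63.2% in B cells and 69 and 70.2% in LPD.

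Of 868 B cell H3K27ac regions with CBP, 62 (7.14%) were lost in LPD, against 28.0% of the 22772 without CBP, a difference of -20.9 percentage points (95% bootstrap interval -22.8 to -18.8). For H3K18ac 3.15 and 11.2% were lost, and for H3K56ac 4.07 and 10.5%. The odds ratios of loss were 0.199 (0.151 to 0.258), 0.263 (0.163 to 0.388) and 0.367 (0.261 to 0.492). For H3K27ac it was 0.416 when peaks had to cover 50% of a region. Among the widest peaks of each list, its upper part, the odds ratios were 0.327, 0.443 and 0.559. Without B cell list 1 or 2 the H3K18ac value was 0.164 or 0.155, and the H3K56ac value 0.215 or 0.221. Regions with CBP held longer B cell peaks, with a median of 1977 against 726 bp for H3K27ac. This length is the mean covered by the 2 B cell lists within a region. Within its quartiles the odds ratios were 0.393 (0.294 to 0.509), 0.467 (0.293 to 0.698) and 0.624 (0.455 to 0.839). The full width of a merged region, which LPD peaks can extend, was not held. Peak length stands in for signal strength, which the lists do not give, so a remaining difference in strength within quartiles was not removed. There was 1 CBP list and none from Crebbp-null cells. It held exactly 1000 peaks, and whether it was cut at that number is not known. Regions without a CBP peak may therefore hold CBP that the list leaves out.

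**Figure D4:**
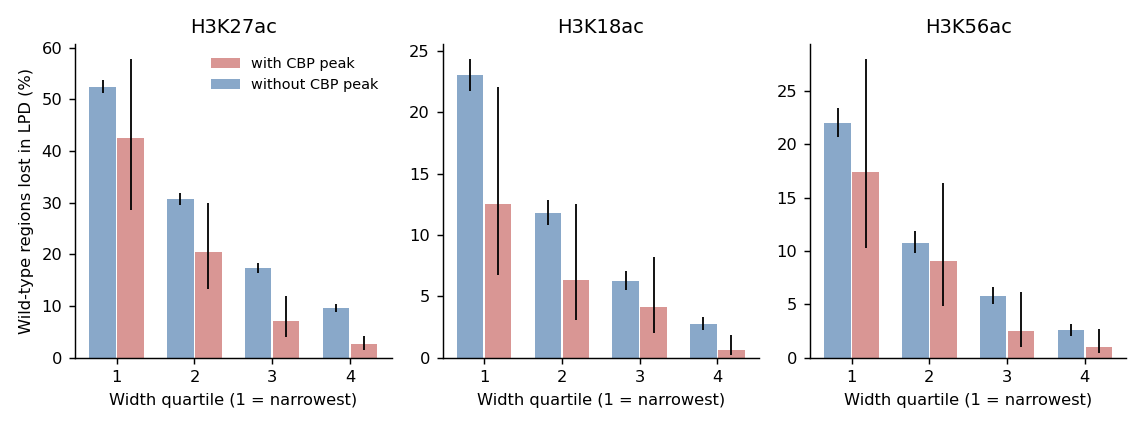
Share of B cell regions lost in LPD (%) with and without a wild-type CBP peak, for the 3 marks. Quartiles of width are of the mean length that B cell peaks cover in a region. Error bars are 95% Wilson intervals for counting error. For H3K27ac in the widest quartile, 2.63% with CBP and 9.67% without were lost.

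How H3K27ac differs between Crebbp-null and wild-type lymphoid progenitors, before disease, was asked with 1 library each, so these values describe 2 libraries and have no replicate check. The gene with the most sequence seen in wild type alone was Prex1, a Rac exchange factor gene (chromosome 2, 166566345 to 166713832), with 13 such regions and 9.08 kb in wild type against 3.20 kb in the null. Sik1 followed with 12 regions and 8.23 against 2.56 kb. The TGF-beta receptor gene Tgfbr2 had 7.20 and 2.43 kb, the semaphorin gene Sema4d 12.9 and 5.40 kb, Cd82 8.61 and 2.40 kb, and Itpkb 7.20 and 1.79 kb. Cd2 had 6.12 and 1.31 kb, and Sgms1, Zmiz1 and B4galt1 completed the 10. Regions seen in the null alone were led by Socs2, a suppressor of cytokine signalling (0.726 kb in wild type and 1.65 kb in the null), Klc1 (1.21 and 2.40 kb) and Inpp4a (none and 0.927 kb). Foxp4, Uaca, Pde5a, Nhsl1, Rassf4, Hmgcll1 and Lgals9 followed, with 0.681 to 0.912 kb of such regions.

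Class II genes lay highest among the 17 gene groups for regions seen in wild-type progenitors alone: 10 of 12 had a region in wild type alone and 0 in the null alone, where matched lists gave 5.86, the 99.7th percentile of 10000 lists. H2-Ab1 had 0.889 kb in wild type and none in the null, H2-Aa 1.35 and 0.208 kb, and Rfxank, the gene of a factor that binds class II promoters, 1.10 and 0.263 kb. T and NK genes had wild-type-only regions at 10 of 11 (percentile 88.1), with Cd5 at 2.19 kb and none. B cell identity genes had them at 13 of 18 (percentile 72.8), cAMP and immediate early genes at 14 of 18 (41.1), NF-kB genes at 12 of 16 (71.7), and proliferation genes at 4 of 18 (31.4). Early B cell genes had wild-type-only regions at 9 of 13 (percentile 18.4) and null-only regions at 4 (percentile 96.2). The 4 were Erg, Sox4, Myb and Rag2, named after their values were seen. Erg also had 6 wild-type-only regions, with 1.81 kb against 0.2 kb null-only, and Sox4 and Myb had 1 each. The null-only regions of Erg, Myb and Rag2 held 0.2, 0.254 and 0.22 kb, near the narrowest peak width of 200 bp.

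Of 17502 progenitor regions, 5434 had a peak in wild type alone, 503 in the null alone and 11565 in both, a log2 ratio of 3.43. The wild-type-only regions were narrow, with a median of 281 bp against 572 bp for shared regions. The share of regions in only one list was 33.9%, and the 6 pairs of B cell or LPD replicates gave 21.4 to 33.6%. With both lists shortened to equal length, the counts were 2469 and 1485.

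Whether the progenitor and LPD differences fell on the same H3K27ac regions was compared over the 41843 merged regions of the 6 lists. Of 3584 regions with a peak in wild-type progenitors alone, 381 were also lost in LPD, where independent lists would share 550 (odds ratio 0.635, 95% bootstrap interval 0.560 to 0.718). This direction depended on the regions counted, in counts added after the data were seen. Over the 11374 regions that had peaks in wild-type progenitors and in both B cell lists, and so could be lost in both, independent lists would share 160 and the odds ratio was 4.32 (3.71 to 4.95). Within quartiles of region width it was 3.21 (2.72 to 3.73). Width here was that of the merged region, which LPD and null progenitor peaks can extend. Regions lost in LPD had a median of 544 bp and kept ones 1229 bp. If narrow, weak regions are missed more often in any list, that alone can raise the odds ratio of losses. This was not removed. Gained regions shared 18 of 375, against 41.4 for independent lists (odds ratio 0.414, 0.197 to 0.673). With a B cell or LPD library left out, the odds ratio of gains ranged from 0.265 to 0.465. Only regions with a peak in at least 1 list were counted, which by itself lowers this odds ratio, so it does not show that gains avoided each other.

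Regions that gained H3K27ac in LPD were rarely acetylated in progenitors. A wild-type progenitor peak lay in 4.54% of them (95% bootstrap interval 3.80 to 5.29) and a null progenitor peak in 2.99% (2.26 to 3.75). For regions lost in LPD the shares were 11.7 and 6.18%, and for kept regions 69.1 and 57.5%. The odds of a wild-type progenitor peak at gained against lost regions were 0.360 (0.291 to 0.436), and 0.3398 (0.276 to 0.411) within quartiles of region width. By the rule, gained regions have no B cell peak, while lost and kept regions have one in both B cell lists. Of wild-type progenitor peaks, 88.4 and 87.9% overlapped the 2 B cell lists, and of null ones 91.3 and 90.8%. The lower shares at gained regions therefore follow in part from the rule.

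**Figure D5:**
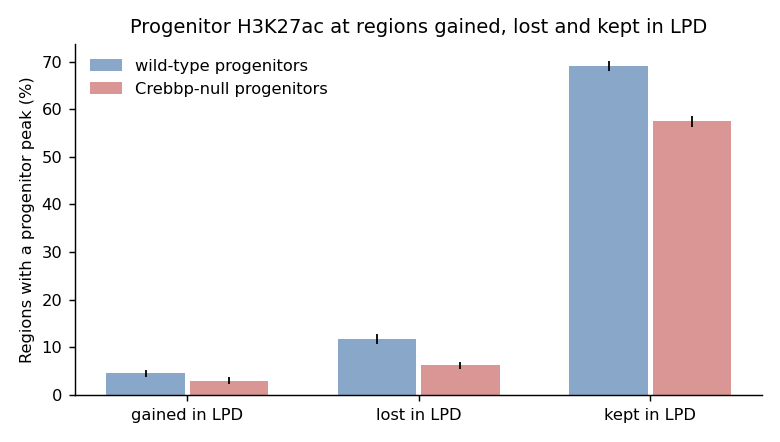
Share of H3K27ac regions gained, lost and kept in LPD that had a peak in the wild-type or the Crebbp-null progenitor list (%); error bars are 95% bootstrap intervals over chromosomes. Kept regions had a wild-type progenitor peak in 69.1% of cases, and gained regions in 4.54%.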

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

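The tests of fewer peaks called in the Crebbp-null lists, of sex in the progenitor pair alone, and of list length differences between replicates were chosen after the results were seen.

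Chromosome Y, whose genes entered no gene comparison, had 27 peaks over the 7 wild-type acetylation lists and 0 over the 7 Crebbp-null lists. The peaks lay at Uty in 7 lists and at Ddx3y, Eif2s3y and Kdm5d in 6 lists each. At the wild-type rate pooled over lists, 33.9 would have been expected in the Crebbp-null lists. This argues against fewer peaks called as the explanation in the 6 LPD lists. It cannot decide this for progenitors, where the wild-type list had only 1 Y peak among 17124 and the null list held 13125 peaks. Xist, whose RNA coats the inactive X of females, had a peak in 1 Crebbp-null list, of 0.559 kb in progenitors, and in no wild-type list, so animals of different sex are a candidate explanation for the progenitor pair. The 6 LPD lists had neither Xist nor Y peaks, which argues against sex alone as the explanation in all 7 lists; loss of a sex chromosome or of Xist acetylation in LPD was not tested.

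The genome length covered differed between marks: its log2 ratio of LPD over B cells was -0.29 for H3K27ac in one direction and 0.88 for H3K18ac and 0.82 for H3K56ac in the other. Without the second LPD list the H3K27ac ratio was -0.03. The difference between marks was not tested. Longer lists from more sensitive LPD libraries remain possible for H3K18ac and H3K56ac, since regions kept in all 4 lists were also wider in LPD in every pair of lists, with a lowest median log2 ratio of 0.0446. Other cell types in the unsorted spleen could not be excluded either: among gained H3K18ac regions the myeloid, T and NK, and erythroid groups lay at percentiles 93.7, 41.2 and 98.3 of matched lists, with a lowest adjusted permutation p of 0.406. A biological difference, through Crebbp loss or the disease, stays open and cannot be told apart from the sort by this design.

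More progenitor regions were seen in wild type alone than in the null alone, a log2 ratio of 3.43. A difference in list length is a candidate explanation, because 1 of the 6 pairs of B cell or LPD replicates, the H3K27ac lists of LPD, reached an absolute log2 ratio of 3.51 without a difference in genotype. With lists of equal length the counts were 2469 and 1485. With 1 library per genotype, loss of acetylation in Crebbp-null progenitors stays open as well.

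The CBP list held 7 peaks on the mitochondrial genome, where the acetylation lists had 0. It held 9 peaks on unplaced sequences, 0.9% of its peaks against 0.0120% in the acetylation lists.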

How the results depend on the processing

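The counts without chromosomes X and Y, and those over only regions that could be lost in both marks or both comparisons, were chosen after the data were seen; all other alternatives were chosen before the data were examined. Such counts for gains were dropped, because the regions counted depended on the outcome. Of the alternative values for the main comparisons, 207 stayed the same in direction and within the limits set, 35 moved and 3 reversed. An odds ratio counted as the same while it and its interval stayed on one side of 1, and some moved by over 1.5 times. Keeping the widest peaks of each list, its upper part, gave 2450 gained and 3323 lost H3K27ac regions, 5923 and 1143 for H3K18ac, 3936 and 799 for H3K56ac, and 2727 wild-type-only progenitor regions. Lists of equal length gave 5214 and 3703 for H3K18ac, 3821 and 2475 for H3K56ac, and 2469 wild-type-only against 1485 null-only progenitor regions. Tiles of 1 kb gave 7592 gained and 11424 lost H3K27ac regions and 17770 gained H3K18ac regions. Joining peaks within 1 kb gave 2962 and 3130 for H3K27ac, 6552 and 1042 for H3K18ac, and 4443 and 967 for H3K56ac. Tiles and joined peaks are other units than the merged regions, so their counts are not directly comparable. Leaving out each library in turn gave 4974 to 10315 gained and 6574 to 10023 lost H3K27ac regions, 12280 to 20914 and 1826 to 3574 for H3K18ac, and 9022 to 12703 and 1720 to 3257 for H3K56ac, since the rule then needs 1 list fewer. The highest gained counts came without the second LPD list of H3K27ac and H3K18ac and without the first of H3K56ac, and the highest lost counts without B cell list 2 for H3K27ac and H3K56ac and list 1 for H3K18ac. Lost H3K18ac regions also passed 1.5 times the count without B cell list 2 (3146) and LPD list 1 (2897), and lost H3K56ac regions without B cell list 1 (2579). The log2 ratio of gained to lost H3K27ac regions ranged from -1.01 to 0.65, and that of H3K27ac peak numbers from -0.14 to 0.072; both reversed without LPD list 2, and the cause was not tested. Tests past the adjusted threshold numbered 1 with lists of equal length, 8 (of 4 gene groups) by Fisher's exact test without matching on region number, and 0 to 2 with a library left out, where omitting B cell list 2 of H3K18ac gave 2 (both of cAMP and immediate early genes, adjusted permutation p 0.0306) and that of H3K56ac 1 (early B cell genes, 0.0204). The odds ratio of progenitor and LPD losses reversed from 0.635 to 4.32 over regions that could be lost in both, and to 3.21 within width quartiles, because regions without a peak to lose no longer counted. Nothing in the labels pairs the replicate numbers; a replicate block left the log2 ratios of peak numbers at -0.03, 0.70 and 0.55, as a mean of paired ratios must with 2 of each. Without read counts, a weaker signal and an absent one cannot be separated.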

Other observations

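The comparisons below were chosen after the data were seen, and their values carry no test unless one is named. Some genes with acetylation at a gene end in all 6 B cell lists had no peak of any mark over their whole span in LPD. There were 45 of these among 6928 genes (0.650%). Among them were the phosphate transporter gene Slc17a4, the carboxypeptidase gene Cpm, Parp8, Rbpms, Lrrk2 and Cd93, a surface marker of immature B cells. Over its span and 1 kb around it, Cpm had 5.30 ± 0.616 kb of H3K27ac in B cells (SD, n = 2), and Rbpms had 3.61 ± 0.242 kb.

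Many genes lost H3K27ac regions and gained H3K18ac regions. Of 11581 genes with both marks, 543 lost H3K27ac without gaining any and gained H3K18ac without losing any, and 6 did the reverse. For H3K56ac the counts were 429 and 6 of 11455. The lymphoid transcription factor gene Ets1 lost 16 H3K27ac regions (11.1 kb) and gained 12 H3K18ac regions (9.24 kb). Ebf1 lost 15 H3K27ac regions (10.5 kb) and gained 5 H3K18ac and 9 H3K56ac regions (4.82 and 5.28 kb). The chemokine receptor gene Cxcr4 lost 5 H3K27ac regions and gained 9 H3K18ac regions, and the desaturase gene Scd1 lost 6 and gained 8. Most of these calls fell on different regions of a gene: 165 merged regions lost H3K27ac and gained H3K18ac, and 36 lost H3K27ac and gained H3K56ac. The lists of H3K18ac and H3K56ac were longer in LPD, which alone favours gains over losses in these counts.

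Regions that changed in all 3 marks had few or no CBP peaks. None of the 2135 regions gained in every mark had one, nor did most of those lost in every mark (6 of 331, 1.81%), against 641 of 8952 (7.16%) of regions kept in every mark. Kept regions also lay more often within 1 kb of a gene end (68.6% against 20.8% of lost regions), where 41.9% of CBP peaks lay, and this was not adjusted for. The widest gained region lay at Grk3 (chromosome 5, 112949916 to 112958168, 8253 bp), followed by regions at Triobp, Rftn1, Cmah and the adrenomedullin gene Adm. The widest lost region lay at Dennd5b (chromosome 6, 149090223 to 149095594, 5372 bp), and the next on chromosome 13 at 83042241 to 83047278, with no gene within reach of the assignment. CBP was profiled in wild-type B cells only, so regions gained in LPD had no acetylation there for a CBP peak to overlap.

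Losses also lay next to each other. The longest run of neighbouring B cell H3K27ac regions without any LPD peak held 12 regions over 14.7 kb at Rras2 (chromosome 7, 114081531 to 114096247). When the 4568 such regions were placed at random among those of the same width quartile and gene-end class, the longest run had a median of 6 regions, and 0.1% of 1000 placements gave a run as long. Random placement ignores that neighbouring regions of one enhancer belong together.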
